A study of Mus musculus with 6 samples.

How the data were processed

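Gene expression was measured in 3T3-L1 cells on 6 arrays, 3 from untreated and 3 from resveratrol-treated cultures. Total RNA was extracted with Trizol, and biotin-labelled target was prepared by the array maker's standard protocol, per the labels' protocols. The deposited values are intensities on a linear scale, 1 per probe set, never negative. The software that summarised the probes is not given in the sources used here. In each column the mean after trimming 2% at each end is 150, so the authors' values carry 1 scaling factor per array and no quantile normalization, as read from the values. On 5 arrays all values have at most 1 decimal, while on control replicate 1 only 0.789% do, so this column was written out in another way. Scaling by 1 factor keeps any difference between arrays that depends on the signal level, and any compression at the bright end would make changes of bright probe sets too small.

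The table holds 45101 probe sets. The 64 control probe sets were left out of the tests. Of the others, 34945 name 1 gene, 932 name several and 9160 name none in the platform annotation, and only probe sets naming 1 gene are named. Symbols were compared through the Entrez number with the RefSeq table of assembly GRCm38.p6, where 34754 probe sets matched and 0 symbols differed. The sources name no genome build for the array, so no coordinates are given. Of the fixed genes, Ccnb1 had no probe set naming it alone.

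Values were used as deposited and turned into log2(intensity + 16). A log2 change or fold on this scale understates changes of dim probe sets. The 60% of probe sets with the highest mean over all 6 arrays were tested, 27022 in number. Resveratrol was compared with control by limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), 2-sided, with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. Every adjusted p of a gene comes from this fit. A gene is represented by its brightest probe set. For 740 changed genes with more than 1 probe set, 134 had probe sets of opposite sign. The 34 gene lists were tested by camera with a preset correlation of 0.01 between genes, with adjustment over the lists, and again with an estimated correlation and by fry. Array similarity was tested by an exact permutation of the group labels.

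Groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Named are the 15 largest rises and 15 largest falls among changed genes whose groups lie apart, up to 4 members of each list with the smallest p, and 18 fixed genes such as Sirt1, Pparg and Nqo1. Alternatives were quantile normalization, offsets of 1 and 64, no filter and the brightest 40% of probe sets, other variance models, array weights, the replicate number as a block, the mean of a gene's probe sets, leaving out probe sets that may cross-hybridise, other set tests, and leaving out each array. After the data were seen, the split of the arrays by spike signal as a block and leaving out probe sets above 4000 were added, and leaving out probe sets that may cross-hybridise, planned for the counts, was also run for single genes.

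The fit was tested on simulated arrays with the levels and spread of these 27022 probe sets, 200 of them changed. It recovered 15 of 67 changes of 0.5 on the log2 scale, 49 of 67 of 1 and 65 of 66 of 2, with 7 false calls among 136, and made 0 calls when nothing was changed. In the data 2209 probe sets were called, so the adjustment was stricter in the simulation. The recovered shares do not carry over to the data. Of 4 lists of 20 genes shifted by 0.4 among 34 simulated lists, camera found 4, with 0 false, with the preset and with an estimated correlation. The simulated genes vary independently, so this says nothing of lists whose genes are correlated. Python 3.11.15 and matplotlib 3.10.9 drew the figures.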

Results

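The transcripts of 3T3-L1 cells, a mouse fibroblast line that can be turned into fat cells in culture, were measured on 6 one-colour oligonucleotide arrays. The arrays came from 3 cultures given resveratrol, a plant polyphenol, and from 3 untreated control cultures. The comparison asks which transcripts differ between treated and untreated cells. The labels give no dose, no length of treatment and no state of differentiation. The number of arrays limits the precision of every value. The 3 arrays of a group are described as replicate cultures, but no label says whether they were grown on separate occasions, so p-values measure the spread between these cultures only.

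The untreated cells already carried high signals for fat cell genes. Fabp4, the fatty acid carrier of adipocytes, had an intensity of 11745 ± 2843 (SD, n = 3) in control cells and 9926 ± 1575 in treated cells. Adipoq, which encodes adiponectin, had 8620 ± 2073 and 6840 ± 754. Dlk1, a marker of preadipocytes, had 3854 ± 306 and 4065 ± 280. None of these 3 differences passed the test, with adjusted p = 0.517, 0.303 and 0.703. These values of Fabp4 and Adipoq lie above 4000. Fabp4 passed with the mean of its probe sets, at -0.39, and without probe sets above 4000, at -0.67. With the split of the arrays by spike signal as a block, its brightest probe set had -0.06 (adjusted p = 0.738). Adipoq passed with quantile normalization, at -0.17, and without control replicate 3, at -0.51. The controls left in that last fit, replicates 1 and 2, are both arrays of brighter spikes. On the arrays of brighter spikes, cell transcripts above 4000 were higher by 0.26 ± 0.06 (SE) on the log2 scale. Within a group the arrays correlated with a mean Pearson r of 0.986, and between groups with 0.978. The difference had an exact permutation p = 0.1, 1-sided, which is the smallest value that 10 splits of 6 arrays allow. The first principal component, with 38.5% of the variance, set the 3 control arrays apart from the 3 resveratrol arrays, and the second, with 18.2%, set control replicate 1 apart.

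Cox8b and Cox7a1, subunits of cytochrome c oxidase, were among the genes that fell the most. Cox8b went from an intensity of 156 ± 39.6 to 7.37 ± 4.88 (SD, n = 3), a log2 change of -2.87 ± 0.21 (SE) with adjusted p = 1.57e-05. Cox7a1 went from 303 ± 24.3 to 40.4 ± 3.23, a log2 change of -2.50 ± 0.11 with adjusted p = 6.93e-07. Ffar4, a receptor for long-chain fatty acids, and Hcar2, a receptor for nicotinic acid, changed by -2.35 and -2.20. Gchfr changed by -2.34, Apoc1 by -2.23 and Klb, the co-receptor for FGF21, by -2.13. Car3, a carbonic anhydrase abundant in adipocytes, fell from 2950 ± 257 to 676 ± 144, a log2 change of -2.12. Pdk1, the kinase that switches off pyruvate dehydrogenase, changed by -2.13, Pla2g2e by -2.10, the mitochondrial adenylate kinase Ak4 by -1.97, and Pck1, an enzyme of glyceroneogenesis, by -1.92. Sema3g, Ankrd37 and Mfap4 complete the 15 deepest falls on the log2 of intensity plus 16, with -1.88, -1.87 and -1.84. Cox8b, Ffar4, Pla2g2e, Pck1 and Mfap4 ended below 11 in the treated cells, where the offset of 16 shrinks a change, so their folds are understated. The order depends on this offset: with an offset of 1, Cox8b had -4.34, Pla2g2e -3.66, Ffar4 -3.62 and Cox7a1 -2.88. These are examples and not the full order at that offset.

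Of 27022 probe sets tested, 2209 changed, 1068 of them higher and 1141 lower with resveratrol. At the level of genes, 1330 of 12630 changed, 672 higher and 658 lower. Falls were the larger: 76 genes were lower and 14 higher by at least 1 on the log2 scale. The 3 arrays of each group lay fully apart for 3816 genes, or 30.2% of those tested, where chance gives 10%. With control replicate 2, resveratrol replicate 1 or resveratrol replicate 2 left out, 1176, 1229 and 1127 probe sets changed. With the split of the arrays by spike signal as a block, a fit chosen after seeing the data, 1896 did. The number was lower than all of these without an intensity trend, as given below with the processing.

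The largest rises were smaller. Fam107a rose from 105 ± 2.33 to 319 ± 50.3 (SD, n = 3), a log2 change of 1.46 ± 0.11 (SE) with adjusted p = 2.82e-05. Id3, an inhibitor of differentiation, rose by 1.23, the acute-phase gene Orm3 by 1.34, and Cxcl1, a neutrophil-attracting chemokine, by 1.13 ± 0.08 with adjusted p = 1.05e-05. Interferon-induced genes made up a part of the list, with Rtp4 at 1.20, Ifit3 at 1.04 and Ifit1 at 1.03, and with Oasl2 rising from an intensity of 44.2 to 105. Retnla rose by 1.02 and Tpte by 1.08. Tubb2a rose by 1.05 through a probe set that may cross-hybridise, and its other probe set had 0.21 and did not pass. Dus2, Serpinb1a, Gtse1 and Rbx1 rose by 1.42, 1.35, 1.20 and 1.17 from control means of 26.4, 9.74, 10.1 and 14.3, close to the dim end of the array. Dus2 rested on uneven controls, at 61.3, 8.4 and 9.6, and its adjusted p was 0.118 without control replicate 2 and 0.0981 without control replicate 3. The call of Rbx1 was lost without a filter on the mean level and without resveratrol replicate 1.

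**Figure D1:**
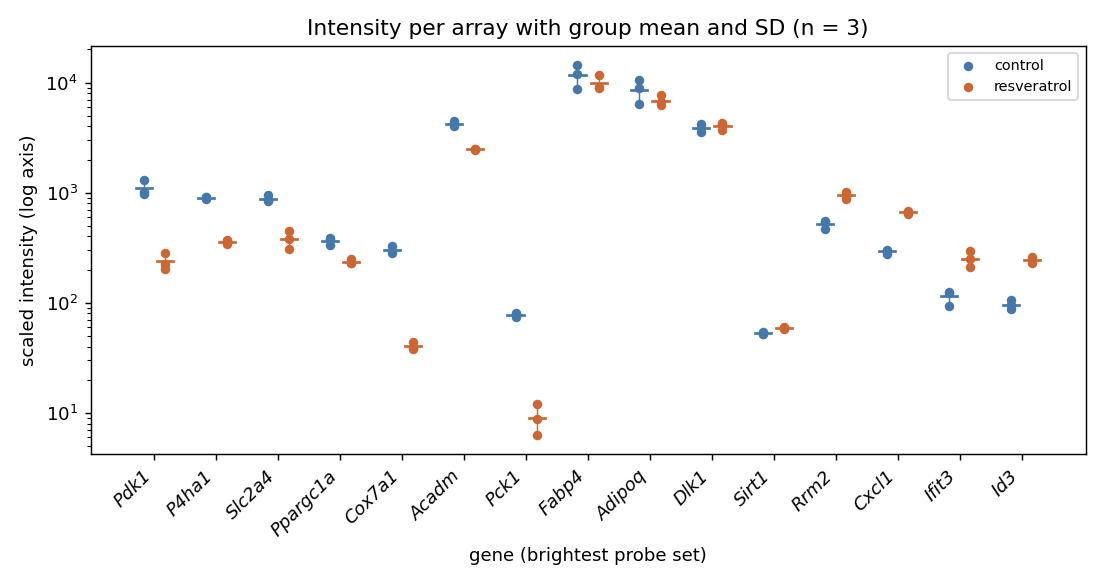
Scaled intensity (log axis) of 15 genes on each of the 6 arrays, by gene on the horizontal axis. Points are arrays, blue for control and orange for resveratrol, horizontal bars are group means and vertical lines are SD (n = 3). Pdk1, Cox7a1 and Pck1 lie lower on all 3 resveratrol arrays, Rrm2, Cxcl1, Ifit3 and Id3 lie higher, and the points of Fabp4, Adipoq and Dlk1 overlap.

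Fixed gene lists gave the following groups, and 13 of 34 lists shifted in the camera test of limma, 3 up and 10 down. None of them passed when the correlation between genes was estimated from the residuals, where the lowest adjusted p was 0.158 and 4 lists had an unadjusted p under 0.05.

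Of 25 genes of glycolysis and of the response to low oxygen, 16 fell, 1 rose and 8 did not pass, and 18 fell and 2 rose when adjusted over the list alone. P4ha1, a collagen prolyl hydroxylase, fell from 898 ± 14.8 to 356 ± 16.3 (SD, n = 3), a log2 change of -1.30 ± 0.07 (SE) with adjusted p = 3.13e-06. Egln3, an oxygen-sensing hydroxylase, changed by -1.59 and Pdk1 and Ankrd37 by -2.13 and -1.87. The list median was -0.50 (adjusted p = 1.67e-13), -0.53 and -0.39 within the arrays of brighter and dimmer spikes and -0.44 with that split as a block, with adjusted p = 0.158 with an estimated correlation.

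Fatty acid oxidation was the list with the lowest median. Of 19 members, 12 fell and none rose, and 16 fell when adjusted over the list alone. Acadm, the medium-chain acyl-CoA dehydrogenase, fell from 4194 ± 209 to 2485 ± 44.8 (SD, n = 3), a log2 change of -0.75 ± 0.08 (SE) with adjusted p = 0.00021. Hadha, the alpha subunit of the trifunctional protein, changed by -0.66, Acadl by -0.66 and the electron carrier subunit Etfa by -0.71. The list median was -0.55 (adjusted p = 4.15e-13), -0.45 and -0.51 within the arrays of brighter and dimmer spikes and -0.49 with the block, with adjusted p = 0.158 with an estimated correlation.

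In the mitochondrial respiratory chain 10 of 33 members fell and none rose, and 13 fell when adjusted over the list alone. Sdha, a subunit of succinate dehydrogenase, changed by -0.70 ± 0.08 (SE, adjusted p = 0.000302), Ndufs1 of complex I by -0.50, Ndufa9 by -0.41 and Uqcrc1 of complex III by -0.52. The list median was -0.26 (adjusted p = 4.18e-10), -0.30 and -0.10 within the arrays of brighter and dimmer spikes and -0.19 with the block, with adjusted p = 0.484 with an estimated correlation and adjusted p = 0.0836 with directional fry. Among 20 genes of mitochondrial biogenesis and sirtuins, 3 fell and none rose, and over the list alone 3 fell and 1 rose. Ppargc1a, the coactivator that drives mitochondrial biogenesis, fell from 366 ± 28.6 to 237 ± 12.6 (SD, n = 3), a log2 change of -0.60 ± 0.09 with adjusted p = 0.00208. Gabpa changed by -0.65 and Nampt, which makes the sirtuin substrate precursor, by -0.39. Sirt1 had a log2 difference of 0.12 ± 0.13 (adjusted p = 0.651), at 52.7 in control and 58.9 in treated cells, and Polrmt one of 0.24 (adjusted p = 0.0862). That list did not shift (median -0.01, adjusted p = 0.225).

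Adipocyte markers fell in part. Of 16 members, 7 fell, 1 rose and 8 did not pass, and over the list alone 9 fell and 1 rose. Slc2a4, the insulin-responsive glucose transporter, fell from 880 ± 61.2 to 380 ± 73.3 (SD, n = 3), a log2 change of -1.19 ± 0.12 (SE) with adjusted p = 0.000172. Gpd1, the glycerol-3-phosphate dehydrogenase, changed by -1.07 and the lipid droplet protein Cidec by -0.57, while Agt, the angiotensinogen gene, rose by 0.96. Pparg, the master regulator of adipogenesis, had -0.26 ± 0.08 (adjusted p = 0.061, and 0.0331 with the spike-signal block) and Cebpa -0.10 (adjusted p = 0.637). Lpl had -0.19 (adjusted p = 0.635), and -0.0033 (adjusted p = 0.99) with the spike-signal block. The probe sets of Fabp4 differed: the brightest gave -0.22, the next -0.14 (adjusted p = 0.689), and those of lowest intensity -0.67 (adjusted p = 0.00129) and -0.51 (adjusted p = 0.00164). With the spike-signal block these probe sets had, in the same order, -0.06, 0.02, -0.66 and -0.51. Pnpla2, the triglyceride lipase, changed by -0.40 (adjusted p = 0.0258) through its brighter probe set, and its other probe set had 0.11. The list median was -0.30 (adjusted p = 6.02e-06), -0.32 and -0.25 within the arrays of brighter and dimmer spikes and -0.27 with the block, with adjusted p = 0.371 with an estimated correlation and adjusted p = 0.0752 with directional fry.

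Of 21 genes of fatty acid and triglyceride synthesis 8 fell and none rose, and over the list alone 10 fell. Thrsp, a lipogenic regulator, changed by -1.60 ± 0.16 (SE, adjusted p = 0.000141), the carbohydrate response factor Mlxipl by -1.42, Acaca, the acetyl-CoA carboxylase, by -0.64, Me1 by -0.49 and Fasn, the fatty acid synthase, by -0.43 ± 0.10 (adjusted p = 0.02). Srebf1 had -0.00 ± 0.11 (adjusted p = 0.993). The list median was -0.28 (adjusted p = 1.54e-06), -0.31 and -0.18 within the arrays of brighter and dimmer spikes and -0.25 with the block, with adjusted p = 0.261 with an estimated correlation. In cholesterol synthesis and uptake 3 of 19 fell, Sqle by -0.72, Idi1 by -0.66 and Pmvk by -0.50, and Srebf2 had -0.25 (adjusted p = 0.0796). Over the list alone 5 fell and 1 rose. That median was -0.16 (adjusted p = 0.000186), -0.15 and -0.13 within the arrays of brighter and dimmer spikes and -0.14 with the block, with adjusted p = 0.261 with an estimated correlation.

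In DNA replication and S phase 15 of 27 members rose and none fell, and 18 rose when adjusted over the list alone. Rrm2, a subunit of ribonucleotide reductase, rose from 519 ± 48.2 to 944 ± 74.0 (SD, n = 3), a log2 change of 0.84 ± 0.09 (SE) with adjusted p = 0.000243. The helicase subunit Mcm5 rose by 0.81, the licensing factor Cdt1 by 0.69 and thymidine kinase Tk1 by 0.89. This median was 0.40 (adjusted p = 4.37e-11), 0.38 and 0.46 within the arrays of brighter and dimmer spikes and 0.40 with the block, with adjusted p = 0.158 with an estimated correlation. In mitosis and G2/M 9 of 28 rose and none fell, and 14 rose over the list alone, among them Cdk1 by 0.49, Birc5 by 0.47, Ccna2 by 0.51 and Ube2c by 0.55. Its median was 0.30 (adjusted p = 1.68e-05), 0.22 and 0.25 within the arrays of brighter and dimmer spikes and 0.30 with the block, with adjusted p = 0.261 with an estimated correlation. Cdkn1a, the cell cycle inhibitor p21, changed by -0.36 ± 0.10 (adjusted p = 0.0495), a call lost with the spike-signal block at adjusted p = 0.0778.

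The interferon response list shifted up, with 8 of 21 members higher, 2 lower and 11 not passing, and 12 higher and 2 lower over the list alone. Usp18 rose from 117 ± 15.9 to 220 ± 5.17 (SD, n = 3), a log2 change of 0.83 ± 0.11 (SE) with adjusted p = 0.000989, and Xaf1 rose by 0.94. The median was 0.36 (adjusted p = 1.68e-05), 0.37 and 0.32 within the arrays of brighter and dimmer spikes and 0.33 with the block, with adjusted p = 0.261 with an estimated correlation. Among 8 tested markers of macrophages, Cd14 rose by 0.47 ± 0.12 (adjusted p = 0.0365) and 7 did not pass, Lyz2 at 0.43 (adjusted p = 0.102), Lyz1 at 0.24 and Csf1r at 0.15, with a further probe set of Csf1r at -0.21. The macrophage median was 0.18 (adjusted p = 0.18). NF-kB and inflammatory genes went both ways, with 3 of 19 higher and 2 lower, and 5 higher and 3 lower over the list alone. Cxcl1, Lcn2 and Csf1 rose by 1.13, 0.70 and 0.50, Hp, which encodes haptoglobin, changed by -1.40, and the list median was 0.02 (adjusted p = 0.52).

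Lists of signalling, clock and matrix genes shifted down as well. Of 23 FOXO target genes 8 fell and 3 rose, and 11 fell and 3 rose over the list alone. Bnip3, a mitophagy receptor that the hypoxia list also holds, changed by -1.32 ± 0.10 (SE, adjusted p = 1.6e-05), Klf15 by -0.82 and Ccng2 by -0.72, and Cited2 rose by 0.35. Its median was -0.22 (adjusted p = 0.00177), -0.32 and -0.17 within the arrays of brighter and dimmer spikes and -0.23 with the block, with adjusted p = 0.158 with an estimated correlation. Of 23 genes of insulin and IGF signalling 5 fell and 1 rose, and 5 fell and 2 rose over the list alone. Igf2 changed by -0.91, Igf1 by -0.65 and Slc2a4 as above, and the kinase gene Akt1 rose by 0.61. That median was -0.08 (adjusted p = 0.043), -0.02 and -0.17 within the arrays of brighter and dimmer spikes and -0.11 with the block, with adjusted p = 0.261 with an estimated correlation. The insulin and IGF shift was lost with the brightest 40% of probe sets and without control replicate 3 or resveratrol replicate 2, and 1 other split of the arrays gave a median of larger size, 0.0815 against 0.0789. Of 17 circadian clock genes 3 fell, Bhlhe40 by -0.71, Rora by -0.39 and Per3 by -0.46 (adjusted p = 0.0626 with the spike-signal block), and none rose, while over the list alone 3 fell and 2 rose. Nr1d1 had 0.36 (adjusted p = 0.06). The clock median was -0.19 (adjusted p = 0.0385), -0.22 and -0.03 within the arrays of brighter and dimmer spikes and -0.16 with the block, with adjusted p = 0.261 with an estimated correlation. It was lost with the mean of a gene's probe sets and without control replicate 1, control replicate 2 or resveratrol replicate 1. In the extracellular matrix list 3 of 28 fell and 2 rose, and 4 fell and 3 rose over the list alone. Lum, Dcn and Postn changed by -0.59, -0.50 and -0.48 and Loxl1 rose by 0.41. The matrix median was -0.15 (adjusted p = 0.0191), -0.10 and -0.11 within the arrays of brighter and dimmer spikes, and the shift was lost with the block (median -0.09, adjusted p = 0.0685), with an estimated correlation (adjusted p = 0.613), with directional fry (adjusted p = 0.321), with quantile normalization and without control replicate 2 or resveratrol replicate 2. For this list 1 other split gave a median of larger size, 0.180.

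**Figure D2:**
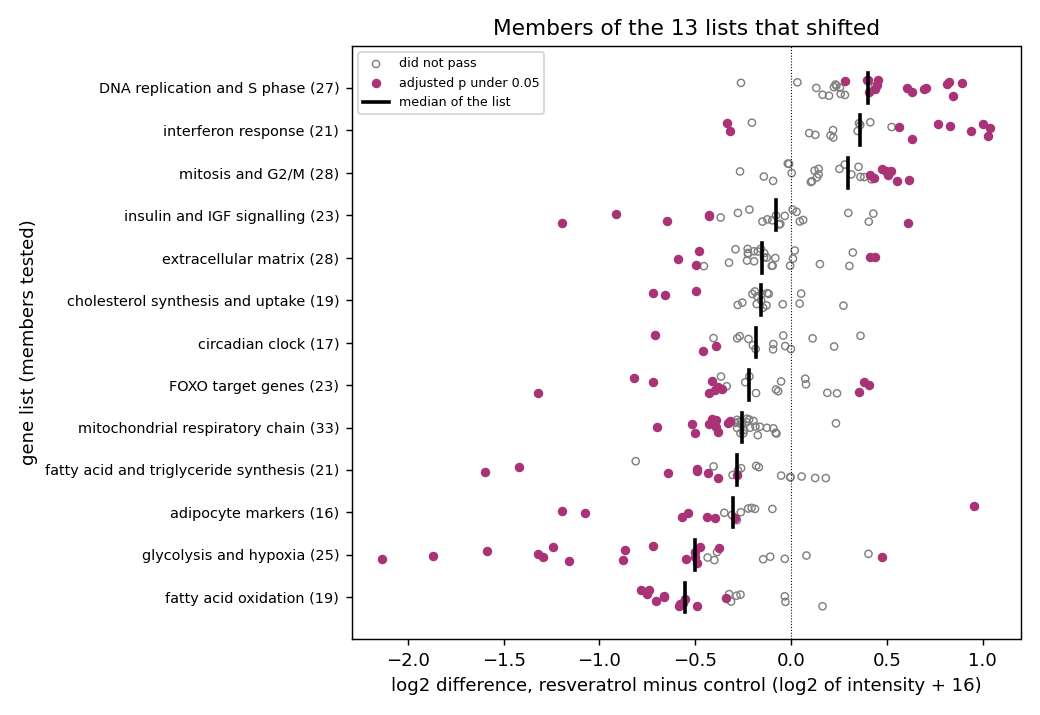
Log2 difference between resveratrol and control (horizontal axis, on the log2 of intensity plus 16) of the members of each of the 13 shifted lists (vertical axis, with the number of members tested). Filled points passed adjusted p under 0.05, open points did not, and black bars are list medians. Fatty acid oxidation has the lowest median, -0.55, and DNA replication and S phase the highest, 0.40.

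The redox and stress lists held single genes that changed without a shift of the list. Of 24 NRF2 target genes 2 rose and 2 fell, and over the list alone 2 rose and 3 fell (list adjusted p = 0.52). Nqo1, a quinone reductase, rose from 206 ± 3.46 to 322 ± 39.1 (SD, n = 3), a log2 change of 0.60 ± 0.10 (SE) with adjusted p = 0.0038, and Ephx1 rose by 0.32. Gstm1 changed by -0.51 and Srxn1 by -0.32, and Hmox1 had -0.16 (adjusted p = 0.233). Among 18 other antioxidant enzymes 3 rose and 4 fell, and 6 rose and 6 fell over the list alone (list adjusted p = 0.548), with Gpx1 up by 0.47, Mt2 at -0.55, Mt1 at -0.46 and Msra at -0.46. Mt1 had 0.0539 without probe sets that may cross-hybridise. The aryl hydrocarbon receptor list had 7 members tested, among them Ahr, the receptor gene itself. Of these, 1 rose, Nqo1 as above, and 2 fell, Tiparp by -0.63 and Ahr by -0.75. The counts were the same over the list alone (list adjusted p = 0.122). Cyp1b1 had -0.14 (adjusted p = 0.372), Tgfbi -0.37 (adjusted p = 0.37) at its brightest probe set, while 2 of its 4 probe sets passed as falls, and Cyp1a1 was too dim to be tested, at 19.4 ± 10.4 and 17.6 ± 7.20. Of 18 genes of the cytosolic heat shock response 4 rose, and 4 rose and 1 fell over the list alone (list adjusted p = 0.158), with Cryab at 0.78, Hsph1 at 0.40, Ahsa1 at 0.31 and Stip1 at 0.31 (adjusted p = 0.0621 with the spike-signal block). Of 20 p53 target genes 3 rose and 1 fell, and 4 rose and 1 fell over the list alone (list adjusted p = 0.957), with Phlda3 at 0.33, Aen at 0.30 (adjusted p = 0.0567 with the spike-signal block) and Sesn1 at 0.38.

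Of 26 genes of the ATF4 amino acid and integrated stress response 2 rose and 4 fell, and 2 rose and 5 fell over the list alone (list adjusted p = 0.548). Trib3 changed by -0.90, Ddit3 by -0.51 and Ddit4 by -0.44, and Shmt2 rose by 0.46. Of 24 endoplasmic reticulum chaperones and genes of the unfolded protein response 1 fell, also over the list alone (list adjusted p = 0.121). That gene was Ero1a, a disulphide oxidase, which fell from 3462 ± 258 to 1047 ± 33.3 (SD, n = 3), a log2 change of -1.71 ± 0.08 (SE) with adjusted p = 1.08e-06. Dnajb9, Herpud1 and Atf6 had -0.21, -0.39 and -0.24 and did not pass. Of 25 autophagy and lysosome genes 3 rose, also over the list alone (list adjusted p = 0.787), Gla by 0.57, Hexa by 0.45 and Ctsk by 0.38 (adjusted p = 0.0575 with the spike-signal block), and Map1lc3a had -0.33 at its brighter probe set, while the other passed at -0.69. Of 31 proteasome subunits 2 rose and 1 fell, and 3 rose and 1 fell over the list alone (list adjusted p = 0.0676, and 0.00599 with the spike-signal block). Psmc3 and Psmc4 rose by 0.40 and 0.58, Psma1 changed by -0.63 and Psmc2 had 0.30 (adjusted p = 0.0323 with the spike-signal block). Of 25 cytosolic ribosomal protein genes 1 rose, Rpl14 by 0.41 (adjusted p = 0.0942 with the spike-signal block), and 4 rose over the list alone (list adjusted p = 0.52, and 0.0088 with the spike-signal block). Rpl12, Rps27 and Rps6 had 0.41, 0.46 and 0.37 and did not pass.

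The lists of preadipocyte markers, early adipogenesis regulators, actin and TGF-beta targets and immediate-early genes did not shift. Of 14 preadipocyte and fibroblast markers 2 rose and 2 fell, and 3 rose and 2 fell over the list alone (list adjusted p = 0.957). Thy1 and Sfrp2 rose by 0.40 each, the call of Sfrp2 being lost with the spike-signal block (adjusted p = 0.0718), Dpt changed by -1.04 ± 0.07 (SE, adjusted p = 1.5e-05) and Fap by -0.88. Of 20 early regulators of adipogenesis 2 rose and 5 fell, also over the list alone (list adjusted p = 0.225), with Cebpd at 0.87, Rxra at 0.41, Klf15 at -0.82 and Ddit3 at -0.51. Of 21 actin cytoskeleton and TGF-beta or SRF targets 4 rose and 1 fell, and 7 rose and 3 fell over the list alone (list adjusted p = 0.172), with Ccn1 at 0.80, Flna at 0.45, Tgfb1i1 at 0.44 and Timp3 at -0.98. Of 25 immediate-early genes 3 rose and 3 fell, and 8 rose and 3 fell over the list alone (list adjusted p = 0.501), with Myc at 0.63, Zfp36 at 0.49, Fosl1 at -1.24 and Jund at -0.40. Among the changed genes named here, Cebpd, Csf1, Xaf1, Ccn1, Igf1, Jund, Rora and Pnpla2 each had a further probe set with the opposite sign. All 4 probe sets of Ccn1 passed, the lowest as a fall at -0.73, and with the mean of its probe sets the gene had 0.07 and did not pass.

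Markers of other cell types were dim and none of the endothelial, skeletal muscle, bone and cartilage or epithelial genes changed, over all probe sets or over the list alone. Their lists had medians of -0.03 in 6 endothelial genes, 0.09 in 5 of skeletal muscle, 0.21 in 5 of bone and cartilage and 0.05 in 5 epithelial genes, with adjusted p = 0.957, 0.889, 0.931 and 0.957. The preadipocyte, autophagy, endothelial and epithelial lists had a median, mean and test that differed in sign. Median intensity was between 31.7 and 34.9 on all arrays, and the 3' to 5' signal ratio of Gapdh between 0.729 and 0.831.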

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

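Tests on the lower share of adipocytes, on the spike split as the source of list shifts, on immune cells, on dim probe sets and on the numbers of probe sets and genes in other splits were chosen only after the results were seen. Groups of 3 arrays are too small for a test of single outlying arrays.

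The hybridisation spikes, bacterial transcripts added to each sample in fixed amount and used in no comparison, were 1.67 times brighter on control replicates 1 and 2 and resveratrol replicate 1 than on the other 3 arrays. An unequal amount of labelled sample behind 1 scaling factor may account for it: the dimmest spike, BioB, differed by 0.86 ± 0.17 (SE over arrays, groups kept), the brightest, CreX, by 0.63 ± 0.08, and cell transcripts of 300 to 900 by -0.02 ± 0.01. Compression of bright signals on the other 3 arrays cannot give the difference of the dim spikes, though cell transcripts above 4000 differed by 0.26 ± 0.06. Within genes above 4000 the brightest probe set's log2 change followed that of the next with a slope of 0.50 (95% bootstrap interval 0.40 to 0.62). For genes of 500 to 2000 the slope was 0.78 (0.72 to 0.83), a difference that compression of bright signals would give. The next probe set had a median level of 3969 in the brighter class and 396 in the other. The slopes therefore do not compare like with like. The brightest probe set had the smaller change in 63 of 111 genes above 4000 and in 723 of 1428 of 500 to 2000, and no biological explanation was tested.

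The fatty acid oxidation and the glycolysis and hypoxia lists were lower with resveratrol. The spike split is argued against, since with the split as a block their mean changes were -0.43 ± 0.05 and -0.64 ± 0.04 (SE over arrays). For the hypoxia list, the mean lay below that of the adipocyte markers by -0.32 ± 0.08, or -0.30 ± 0.05 against markers at or below 4000. This cannot decide on a lower share of adipocytes among the cells, since the markers did not fall alike. Of 16 markers 7 fell, 1 rose and 8 did not pass. Slc2a4 changed by -1.19, and Fabp4 by -0.22 at its brightest probe set and -0.67 at a dimmer one. The marker mean is thus not the most that a lower share could give. For fatty acid oxidation the difference was -0.11 ± 0.08, and -0.08 ± 0.04 against markers at or below 4000, so a share of adipocytes and an effect within adipocytes cannot be told apart. An effect of resveratrol, which the design names, stays open.

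The interferon list was higher with resveratrol. Noise of dim probe sets is argued against, since the list passed with the brightest 40% of probe sets and with an offset of 64. The higher adjusted p was 7.04e-05, from camera with the preset correlation. With an estimated correlation the list had adjusted p = 0.261, so this holds under the preset only. Macrophages or other immune cells among the cells stay open: the macrophage list lay below the interferon list by -0.20 ± 0.09 (SE over arrays), but its markers are dim and Cd14 rose. Tyrobp, at 21.0 in control and 10.1 in treated cells, and Ptprc, at 10.6 and 6.40 with a further probe set at 3.43 and 5.63, were too dim to be tested. An effect of resveratrol stays open too.

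Among probe sets that name no single gene, 175 of 4198 tested changed, 92 higher and 83 lower.

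The 10 possible splits of 6 arrays are too few for a share under 0.05. In every split but the real one, both sides hold control and resveratrol arrays. A treatment difference then adds to the spread within sides, and part of it stays in the list medians. The numbers from those splits are therefore no rate of calls in the absence of a difference. The real split called 2209 probe sets and 1330 genes, the highest of the other splits 0 and 0, and at an unadjusted p under 0.05 the numbers were 5857 and at most 1457 probe sets, so 1 of 10 splits gave as many. Of gene lists the real split shifted 13, and 3 of the 10 splits shifted as many. The highest other, 14, came from the split that follows the spike signal. With that split as a block 14 lists shifted, 12 of them among the 13. The median of 11 of the 13 lists was larger in size in the real split than in any other, but by little for some: 0.301 against 0.297 for adipocyte markers, 0.257 against 0.247 for the respiratory chain and 0.282 against 0.261 for fatty acid and triglyceride synthesis.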

How the results depend on the processing

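The settings with the spike-signal block, without probe sets above 4000, and, for single genes, without probe sets that may cross-hybridise were chosen after seeing the data. Without a filter the number of probe sets changed was 1396 and that of genes changed 848, and without an intensity trend they were 861 and 518. More probe sets enter the adjustment without a filter, but the cause was not tested for either setting. With each array left out in turn, 1127 to 1956 probe sets, 691 to 1165 genes and 11 to 14 lists passed, from fewer arrays. Lists shifted numbered 0 with an estimated correlation, 11 with directional fry and 29 with mixed fry, which asks another question. Directional fry lost adipocyte markers, the respiratory chain and extracellular matrix and added aryl hydrocarbon receptor targets. Replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at -0.06, -0.02 and 0.09, and with the replicate block 1894 probe sets, 1128 genes and 13 lists passed. Of 128 named genes that changed, 76 passed under every alternative that gave a value for them, 68 of them with a value under all, and 10 of the 13 lists passed under all but the other set tests; the exceptions were extracellular matrix, insulin and IGF signalling and circadian clock. Calls of Aen, Csf1, Dcn, Ccn1, Igf1, Jund, Rora, Per3 and Pnpla2 were lost with the mean of a gene's probe sets, and those of Tubb2a, Mt1 and Sesn1 without probe sets that may cross-hybridise. The sign turned for Pnpla2, at 0.11 without probe sets above 4000, and for Mt1, at 0.0539 without probe sets that may cross-hybridise, since another probe set then stands for the gene. Array similarity kept its direction without a filter and with quantile normalization, with within minus between at 0.00379 and 0.00731 against 0.00728. Signal over background limits dim genes.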

Other observations

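Lists in the next 2 paragraphs were chosen only after the main results were seen, so their tests are not independent evidence. Their p-values are adjusted over the 34 fixed and 8 added lists together, where 1 of the 8 passed with an estimated correlation. Adjusted over the 8 added lists only, 7 passed. The tests on mitochondrial ribosomal proteins and on Hif1a, Epas1 and Arnt were written before their values were seen.

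Of 20 genes for breakdown of branched-chain amino acids 16 fell and none rose, with Hibch at -0.79, the dehydrogenase subunit Bckdhb at -0.66 and the transaminase Bcat2 at -0.72, and a list median of -0.60 (adjusted p = 0.0732 with an estimated correlation). In the tricarboxylic acid cycle list 12 of 20 fell and none rose, with Sucla2 at -0.51 and Pdhb at -0.50. Its median was -0.37 (adjusted p = 0.126 with an estimated correlation). This list also holds genes of pyruvate dehydrogenase, such as Pdhb and Pdha1. It shares Sdha, Sdhb, Sdhc and Sdhd with the respiratory chain list. Of 28 genes known as HIF targets outside glycolysis 20 fell and 1 rose, with Fam162a at -1.38, Selenbp1 at -1.32 and Kdm3a at -0.84. The other probe set of Fam162a had -0.27 and did not pass. The list median was -0.69 (adjusted p = 0.017 with an estimated correlation). The glycolysis and hypoxia list holds some of these genes too, among them P4ha1, Egln3, Ankrd37 and Bnip3. The falls of those genes and of Ero1a and Ak4, also in the HIF list, were given above. The result of the HIF list is thus in part a restatement of them. Of 9 brown adipocyte thermogenic genes 5 fell, among them Kcnk3 at -0.79 and Elovl3 at -0.65 (adjusted p = 0.0775 with the spike-signal block), and the median was -0.60 (adjusted p = 0.0732 with an estimated correlation). That median is the change of Ppargc1a, already given above. The members differed widely, with a mean of -0.87 and an SD over members of 1.07.

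Of 20 genes of ribosome biogenesis and the nucleolus 12 rose and none fell, with Nop56 at 0.64, Fbl at 0.47 and Ddx21 at 0.46 and a median of 0.43 (adjusted p = 0.0524 with an estimated correlation). In nucleotide synthesis 8 of 19 rose, with Nme1 at 0.96 and Ctps at 0.54, and Impdh1 fell by 0.96, with a median of 0.28 (adjusted p = 0.179 with an estimated correlation). Of 10 BMP and inhibitor of differentiation targets 4 rose, all of them Id genes, namely Id3 at 1.23, Id2 at 0.68 (adjusted p = 0.0894 with the spike-signal block), Id1 at 0.64 and Id4 at 0.49, with a median of 0.32 (adjusted p = 0.124 with an estimated correlation). Of 11 tubulins and microtubule motors 4 rose, with Tuba1a at 0.67 and Tubb2a at 1.05 (0.21 and not passing at its other probe set) and a median of 0.26 (adjusted p = 0.0804 with an estimated correlation).

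A hypothesis is that the lower levels of genes of fatty acid oxidation, the tricarboxylic acid cycle and branched-chain amino acid breakdown may be part of a fall of nuclear genes for mitochondrial proteins in general. The 76 genes of mitochondrial ribosomal proteins had a mean log2 change of 0.0266 ± 0.0554 (SE over arrays), 3 rose and none fell. This argues against a fall that reaches this class. Of 33 respiratory chain genes, however, 32 had a change below 0, with a median of -0.26. These genes are not independent, with an estimated correlation of 0.73 between them. Their median was -0.19 with the spike-signal block, and -0.30 and -0.10 within the arrays of brighter and dimmer spikes. A fall shared by several other classes therefore stays open. A further hypothesis is that genes induced by hypoxia are lower because Hif1a, Epas1 or Arnt transcripts are. The brightest probe sets had 0.00 ± 0.08, -0.09 ± 0.09 and -0.11 ± 0.09 (SE), but the dimmer probe set of Epas1 changed by -0.35 ± 0.09 (adjusted p = 0.0397), so the test leaves it open. Protein levels were not measured here.

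The 18S ribosomal RNA probe sets had a mean intensity of 287 on control replicate 1 and between 98.5 and 131 on the other 5 arrays. Without control replicate 1, 1956 probe sets changed.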
